A study of Caenorhabditis elegans with 2 samples.

How the data were processed

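Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed with an anti-GFP antibody on whole hermaphrodite young adults of Caenorhabditis elegans, 63 h after release from L1 starvation, from a line that stably expresses MES-4 with a GFP tag at its C terminus. MES-4 is a histone H3 lysine 36 methyltransferase needed for germline development. Chromatin was sheared by sonication, per the labels. There was 1 group with 2 biological replicates, so no contrast between groups existed and the comparisons set peak positions against the genome, against annotation or against the other replicate. The labels name the replicates as biological, and nothing further on their cultures was used here.

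The deposited values were lists of peaks, on the ce10 and ce11 builds, and 8 such lists were read. Per the deposited descriptions of the files, the authors called relaxed lists of peaks and background for each replicate and for the pooled replicates against a control, and kept the reproducible peaks by the irreproducible discovery rate (IDR). The aligner, peak caller, their versions and the IDR threshold are not given in the sources used here. Each deposited peak carries a signal value, which was used to rank peaks within a list because its scale differed between lists, and a −log10 q value. The column for p held -1 throughout, which marks a value not given. The signal value of a peak is the authors' own. Read depth per sample is unknown from these lists, and the control and an immunoprecipitation from untagged animals were not analysed here. Intervals on shares are exact 95% Clopper-Pearson intervals and cover counting error only.

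Coordinates are 1-based on ce11, the name of the WBcel235 assembly used for annotation (genes from Ensembl release 115, tRNA isotypes from RefSeq), and no ce11 peak ended beyond its chromosome there. The ce10 lists were used for counts per chromosome alone, and no coordinates were converted. The 20 mitochondrial peaks were left out of the comparisons because gene and chromosome shares refer to the 6 nuclear chromosomes, which left 440 nuclear reproducible peaks. A summit was assigned to a promoter when it lay from 500 bp upstream to 100 bp downstream of an annotated 5' end of a protein-coding gene, and to a gene body when it lay between the first and last annotated base. A gene was called bound when a summit lay in its body or up to 500 bp upstream. A peak was placed at a tRNA gene, or otherwise at a snRNA or snoRNA gene, when its summit lay within 220 bp, a distance that spans the median peak width of 440 bp around the summit. This placement was chosen after the data were examined. Small RNA genes here means tRNA, snRNA and snoRNA genes alone, so peaks at other noncoding RNA genes count as lying elsewhere. The other definitions, the tests of the X, chromosome centre, promoter and gene body shares and of the replicates, and the 20 gene lists with their test were fixed before the data were examined. Exon and intron shares were planned without a test.

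Shares were tested with two-sided permutation tests of 100000 circular rotations of the peaks, along the concatenated chromosomes for the X and chromosome centre shares and within each chromosome for the others. The smallest p these can give is 1e-05. Gene lists were tested with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 20 lists, against 19973 protein-coding nuclear genes or, for noncoding RNA lists, against 46890 annotated nuclear genes. A summit can make several overlapping genes bound, so genes were not fully independent in these tests. Replicates were compared by overlap of at least 1 bp among the 440 nuclear peaks with the highest signal in each, and by correlation of signal across regions with 10000 shuffles. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No nuclear peak of replicate 1 had the same start, end and summit as a peak of replicate 2. However, 99.88% of replicate 1 peaks were 440 bp wide and 99.81% of replicate 2 peaks 430 bp. Identical peaks were therefore hardly possible, so this cannot show whether the lists are independent.

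The tests were tested on simulated data with 440 peaks per set, in 60 sets without and 60 sets with a planted effect. The X share test gave p under 0.05 in 4 of the 60 sets without an effect and in 55 of those with 50 peaks added on X. The gene body test gave 2 and, with 60 peaks planted in genes, 46. The test of ribosomal protein genes gave 0 and, with 8 planted peaks, 60. Those 8 peaks lay in 8 different ribosomal protein genes, so that call followed from the planting. The other simulated peaks were placed independently along the genome. Real peaks may lie in groups, so the rates above need not carry over to them.

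The genes named in the text follow a rule fixed beforehand. It takes mes-4 and its neighbours, the bound genes of the 20 peaks with the highest signal, up to 4 bound members of each list and, since more than 10 genes on X were bound, the 5 with the highest signal on X. Because 18 of the 20 highest signals in the whole list were mitochondrial, the second part was applied to nuclear peaks. Genes named outside this rule are said to be so. Alternatives were a stricter and a looser peak set, each replicate alone, other windows and overlaps, length-matched random lists, autosomal genes alone and the ce10 lists. Leaving out peaks at small RNA genes, the tests of exon and intron shares, and the comparisons at tRNA, snRNA and snoRNA genes other than the gene lists were added after the data were examined.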

Results

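The series measured where GFP-tagged MES-4 was recovered on chromatin in young adult hermaphrodites, in 1 group with 2 biological replicates. The reproducible list held 460 peaks on ce11, of which 440 were nuclear and 20 were mitochondrial. The nuclear peaks formed 432 separate regions after overlapping peaks were merged. The relaxed lists held 15392 peaks for replicate 1, 14970 for replicate 2 and 12028 for the pooled replicates. Of the 440 nuclear reproducible peaks, 439 overlapped a relaxed peak of replicate 1 and 440 overlapped one of replicate 2. All 460 reproducible peaks were also the 460 regions with the highest signal in the pooled list.

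The first question was whether both replicates recovered the same sites. Among the 440 strongest nuclear peaks of each replicate, 265 of replicate 1 (60.2%, 95% interval 55.5 to 64.8) overlapped one of replicate 2, against 0.40% over rotations (p = 1e-05, permutation test, the smallest possible). The strongest nuclear peak was the same in both, an intron of pxn-1, which encodes a peroxidasin, next to the snoRNA gene ZK994.7 (V, 8500408 to 8500687). It ranked 1 in replicate 1 and 1 in replicate 2. The next, at the snoRNA gene C51F7.4 in an intron of frm-7 (V, 12303522 to 12303752), ranked 2 in both. Across 5602 pooled regions that overlapped a peak of both replicates, signal correlated with Spearman's rho 0.40 (permutation p = 0.0001, the smallest possible) and with Pearson's r 0.60 on the log2 scale (permutation p = 0.0001). These are correlations across regions, which are not independent replicates. The overlap fell to 36.0% among the top 5000 peaks of each replicate.

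The next comparison asked what the reproducible peaks lay on. Genes of small structural RNAs held most of them. Of the 440 nuclear peaks, 204 (46.4%, 41.6 to 51.1) had their summit at a tRNA gene, against 0.35% over rotations, and 87 (19.8%, 16.2 to 23.8) lay at a snRNA or snoRNA gene, against 0.25% (both p = 1e-05, permutation test, the smallest possible). When each peak was counted once, 204 lay at tRNA genes, 86 at snRNA or snoRNA genes and 150 elsewhere. The 150 still include peaks at other noncoding RNA genes, such as those of RNase P RNA, miRNAs and piRNAs. The gene of the RNase P RNA, rpr-1, nested in an intron of ints-8, carried the third strongest nuclear peak (I, 13463804 to 13464025, signal 252.99), and the microRNA gene cel-mir-51 the peak of rank 20 (IV, 11025871 to 11026310).

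The median summit lay 37.5 bp downstream of the 5' end of the nearest tRNA gene (quartiles 4 and 70.5 bp) and 177 of 204 lay within 100 bp of it, where the median tRNA gene was 72 bp long. At several of the strongest snoRNA genes the summit lay just upstream, by 26 bp at ZK994.7, 50 bp at ZK265.10 and 87 bp at W03C9.9. Of 612 tRNA genes, 225 (36.8%, 32.9 to 40.7) had a summit within 220 bp, as did 68 of 346 snoRNA genes (19.7%, 15.6 to 24.2) and 18 of 129 snRNA genes (13.95%, 8.48 to 21.2). Among tRNA isotypes none differed from the others after adjustment over 21 isotypes. The alanine genes came closest, with a summit within 220 bp of 21 of 34 (Fisher's exact p = 0.00309, adjusted p = 0.0648), while histidine genes had 2 of 20 (adjusted p = 0.0967).

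**Figure D1:**
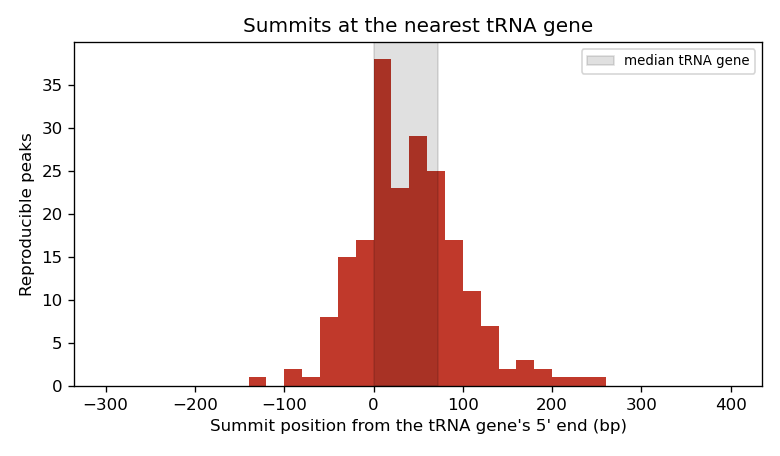
Position of 204 reproducible summits from the 5' end of the nearest tRNA gene, in bp, with peaks counted per bin on the vertical axis and the median tRNA gene length of 72 bp shaded. The median summit lay at 37.5 bp.

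The X chromosome was compared with the autosomes because MES-4 is known as a protein of autosomes. X held 126 of the 440 nuclear peaks (28.6%, 24.5 to 33.1), against 17.7% over rotations (p = 0.0389, permutation test), and 1587 of the 11568 other pooled regions (13.7%, odds ratio 2.52, Fisher's exact p = 1.78e-15). Fisher's exact test takes peaks as independent, which the rotations do not, so where peaks cluster its p overstates the evidence for the X excess. The peaks at tRNA genes made up this excess: 115 of 204 (56.4%, 49.3 to 63.3) were on X, where 276 of the 612 tRNA genes (45.1%) lie. Peaks at snRNA or snoRNA genes had 2 of 86 on X (2.33%, 0.283 to 8.15) and the remaining peaks 9 of 150 (6%, 2.78 to 11.1), below the 17.7% of the genome, although rotations gave p = 0.0869 and p = 0.126 (permutation tests). Of the 475 snRNA and snoRNA genes, 439 lie on autosomes, so a low X share is expected of their peaks. In other peak sets the X share lay below rotations past the threshold for peaks away from small RNA genes in the top 1000 pooled regions (35 of 565, 6.19%, permutation p = 0.0052), but not in replicate 1 (permutation p = 0.0645) or replicate 2 (permutation p = 0.0608). For snRNA and snoRNA genes it did so in replicate 1 (1 of 86, permutation p = 0.0363), but not in replicate 2 (permutation p = 0.0608) or the top 1000 (permutation p = 0.0617). tRNA genes on X had a summit more often than those on autosomes, 127 of 276 (46.0%) against 98 of 336 (29.2%, odds ratio 2.07, Fisher's exact p = 2.39e-05). Odds ratios were 2.05 in replicate 1 and 2.54 in replicate 2. In the top 1000 pooled regions the gap was narrower, with 61.6% on X and 50.6% on autosomes, and was not tested.

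The strongest peaks on X marked tRNA genes. C04A11.t1, a leucine tRNA gene, had signal 212.6 (X, 13665390 to 13665829). The alanine tRNA genes F15G9.t1 and F15G9.t2, in an intron of him-4, which encodes hemicentin, shared a peak of signal 200.7 (X, 9743407 to 9743846). Of the 9 peaks on X away from small RNA genes, that with the highest signal lay at T13C5.6 (X, 6207654 to 6208093, signal 157.8), a gene named here after its value was seen. The X share was 19.7% in the top 1000 pooled regions (p = 0.58, permutation test) and 12.7% (10.04 to 15.7) among regions of rank 441 to 1000.

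**Figure D2:**
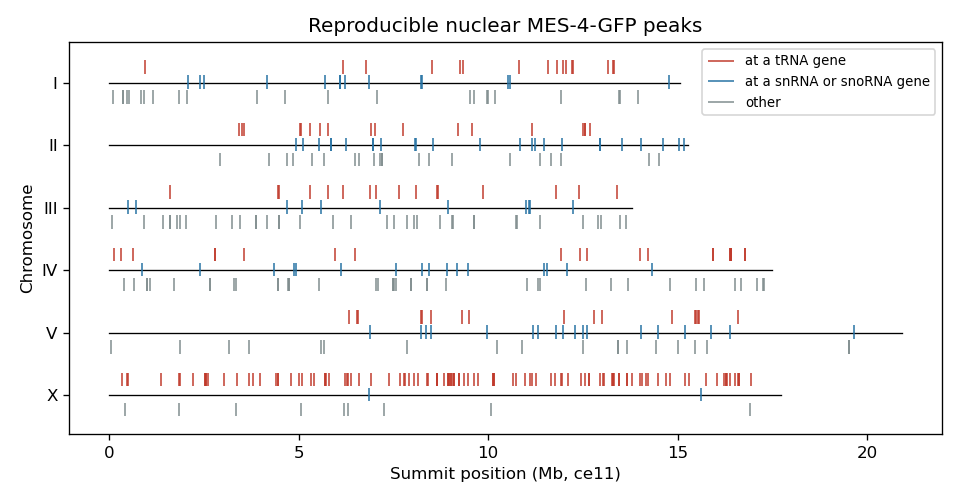
Positions of the 440 nuclear reproducible peaks along the chromosomes in Mb on ce11, split into peaks at tRNA genes, at snRNA or snoRNA genes, and elsewhere. Of 204 peaks at tRNA genes, 115 lie on X, and of 150 elsewhere, 9 do.

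**Figure D3:**
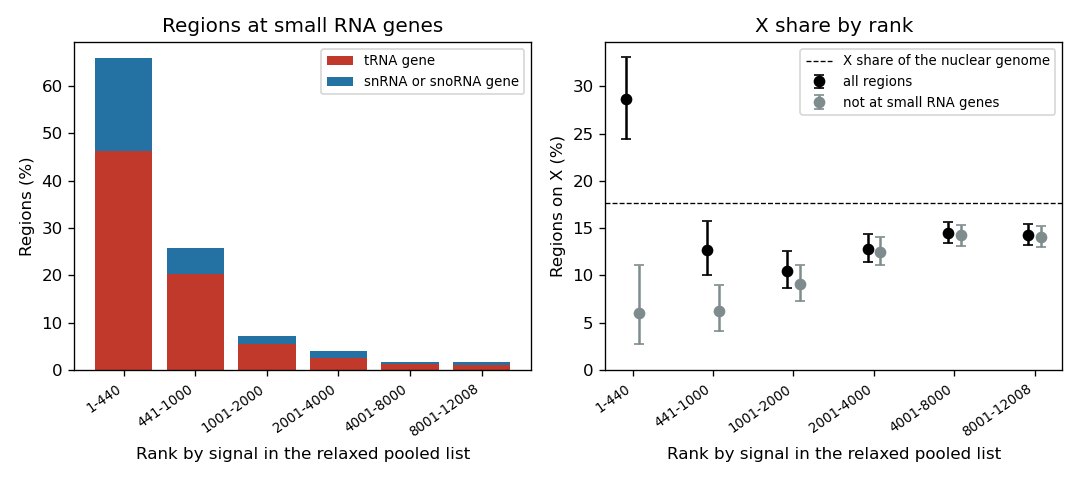
Left, percent of pooled regions at tRNA genes and at snRNA or snoRNA genes, by rank of signal; right, percent of regions on X with exact 95% intervals, for all regions and for those not at small RNA genes, with the X share of the nuclear genome (17.7%) dashed. The share at tRNA genes falls from 46.4% to 1.12% from the first to the last bin.

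The chromosome centre share was 40.0% (35.4 to 44.7), against 33.3% over rotations (p = 0.121, permutation test). Promoters of protein-coding genes held 97 of the 440 peaks (22.05%, 18.3 to 26.2), against 13.7% over rotations (p = 1e-05, permutation test, the smallest possible), and rpl-3, rpl-20, his-67 and his-68 were among the genes with a summit upstream. Gene bodies held 214 (48.6%, 43.9 to 53.4), fewer than the 61.9% over rotations (p = 1e-05, permutation test), but by any overlap of the peak with a gene the share was 65.9% against 67.8% and the call ended (p = 0.435, permutation test). Exons held 14.1%, against 28.8% (p = 1e-05), and introns 34.5%, against 33.1% (p = 0.554, permutation tests). Gene bodies held 72.5% (70.4 to 74.4) of pooled regions of rank 2001 to 4000, compared with 48.6% of the 440 strongest. The 150 peaks away from tRNA, snRNA and snoRNA genes had a promoter share of 38.0% against 14.2% over rotations (p = 1e-05, permutation test). Their exon share was 32.0% against 29.8% (p = 0.6), and their intron share 17.3% against 34.4% (p = 4e-05, permutation tests).

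Gene lists fixed before the data were examined were compared with all genes. In all, 289 of 19973 protein-coding genes (1.45%) were bound. Of the 20 lists, 7 differed from the background, with tRNA genes (173 of 612, odds ratio 32.6, adjusted p = 1.05e-167) and snRNA and snoRNA genes (78 of 475, odds ratio 13.9, adjusted p = 1.54e-54) bound most often by Fisher's exact test. Length-matched lists gave 38.5 and 15.6 expected (both adjusted p = 0.0005, permutation test). Of the 81 ribosomal protein genes, 8 were bound against 1.17 expected (odds ratio 7.65, Fisher's exact test, adjusted p = 0.000112). They were led by rpl-3, with a summit 287 bp upstream (III, 3867477 to 3867675, signal 192.7), rpl-20 (IV, 4749846 to 4750285, 162.0), rpl-35 (III, 7854467 to 7854906, 125.9) and rpl-15 (IV, 654707 to 655146, 123.7). None of these 8 peaks lay at a small RNA gene, but 2 of the 8 genes had the summit inside the gene body, and counting gene bodies alone ended the call (odds ratio 2.49, Fisher's exact test, adjusted p = 0.348).

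Among germline lists, 3 of 30 germ granule and germline small RNA genes were bound (odds ratio 7.64, Fisher's exact test, adjusted p = 0.0304), each with its summit in the 3' UTR. These were hrde-1, which encodes a nuclear Argonaute (III, 4172244 to 4172683, signal 145.7), the Argonaute gene csr-1 (IV, 7961776 to 7962215, 98.4), and mip-2 (V, 13669194 to 13669633, 78.3). The call ended with length-matched random lists (0.557 expected, permutation test, adjusted p = 0.063) and among the upper 220 peaks (1 of 30, odds ratio 4.99, Fisher's exact test, adjusted p = 0.342). In both the direction was the same. The call held with each replicate alone, in the top 1000 pooled regions, for gene bodies alone, by any overlap and among autosomal genes. Without peaks at small RNA genes the same 3 genes stayed bound, against fewer bound genes in all (odds ratio 17.8, Fisher's exact test, adjusted p = 0.00599). Meiosis genes had 3 of 36 bound (odds ratio 6.25, Fisher's exact test, adjusted p = 0.043), which were brd-1, zhp-3 and the synaptonemal complex gene syp-4, and all 3 summits lay at small RNA genes, the first 2 at tRNA genes and that of syp-4 in an snRNA gene. No meiosis gene was bound once those peaks were left out, and the call also ended with length-matched lists (0.64 expected, permutation test, adjusted p = 0.066) and, by Fisher's exact test, without replicate 2 (2 of 36, odds ratio 3.84, adjusted p = 0.172), among the upper 220 peaks (odds ratio 8.56, adjusted p = 0.0569), for gene bodies alone (odds ratio 5.81, adjusted p = 0.128) and by any overlap (odds ratio 4.42, adjusted p = 0.0902). The direction was the same in these settings, where 2 or 3 genes were bound, so these lost calls do not show that the difference went away. Oogenesis genes had 2 of 38 bound, the eggshell genes cbd-1 (in its 3' UTR) and cpg-1 (Fisher's exact test, adjusted p = 0.19).

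The other lists did not pass the adjusted test in the main set, apart from those bound less often. Cell cycle genes had 2 of 35 bound (mix-1 and cye-1), histones 3 of 72 (his-67 and his-68, which share 1 peak, and his-60), neuron markers 2 of 34 (cat-1 and unc-104), cuticle and hypodermis markers 4 of 172 (col-85, col-99, col-19 and col-176), dosage compensation 1 of 11 (mix-1), heat shock proteins 1 of 23 (hsp-1), sperm 1 of 76 (spe-9) and miRNA genes 2 of 261. None of 28 chromatin regulators, 29 muscle markers, 27 intestine markers or 20 rRNA genes was bound. With 0.42 expected among muscle markers and 0.39 among intestine markers, a lower share could not be detected at these list sizes. The strongest summits at mix-1, cye-1, cat-1, unc-104, col-85, col-99 and spe-9 lay at tRNA or snoRNA genes in or near the named gene. At unc-104 a weaker reproducible peak lay away from small RNA genes (II, 7001400 to 7001839, signal 77.3). Neuron markers thus kept 1 of 34 bound when peaks at small RNA genes were left out. Several of these lists, and oogenesis, were bound more often in alternative sets by Fisher's exact test. Cell cycle genes and neuron markers passed with each replicate alone (adjusted p = 0.0333 for both without replicate 1 and 0.0395 for both without replicate 2) and oogenesis without replicate 1 (adjusted p = 0.0374, Fisher's exact test). Histones, with 3 genes bound by 2 peaks, passed among the upper 220 peaks (adjusted p = 0.0454) and without peaks at small RNA genes (adjusted p = 0.0435, Fisher's exact tests). In the top 1000 pooled regions oogenesis, cell cycle, histones, cuticle and hypodermis markers, dosage compensation and heat shock proteins passed (adjusted p from 0.00164 to 0.0226, Fisher's exact tests). Cell cycle and dosage compensation no longer did in those regions without peaks at small RNA genes. Their odds ratios were 3.76 after 4.49 (adjusted p = 0.0888) and 8.91 after 10.09 (adjusted p = 0.0515, Fisher's exact tests). Their direction was the same there, so these lost calls do not show that the difference went away. In the reproducible list without such peaks, 0 of 35 cell cycle and 0 of 11 dosage compensation genes were bound. With 0.223 and 0.0699 expected, a lower share could not be detected there. Small counts moved with the replicate used: sperm genes had 0 bound without replicate 1 and 4 without replicate 2 (odds ratio 3.64, Fisher's exact test, adjusted p = 0.0568), and cuticle and hypodermis markers 1 and 5. Chemoreceptor genes had 5 of 1309 bound against 18.9 expected (odds ratio 0.25, Fisher's exact test, adjusted p = 0.000706), although length-matched lists gave 12.6 expected and adjusted p = 0.0657 by permutation. piRNA genes had 8 of 15363 against 237.5 expected (Fisher's exact test, adjusted p = 9.02e-110), and against 92.5 expected with length-matched lists (permutation test, adjusted p = 0.0005). The Fisher test takes no account of length. piRNA genes make up most of the shortest genes, so the matched lists drew largely from piRNA genes themselves. The rest came from other short genes, tRNA genes among them, so this match cannot show a shortage at piRNA genes. The miRNA genes did not differ in the main test, and their alternatives went both ways. They were bound less often than length-matched lists, which draw from all gene types, tRNA and snoRNA genes among them (14.5 expected, permutation test, adjusted p = 0.0024), and more often in the top 1000 pooled regions without peaks at small RNA genes (8 against 3.17 expected, Fisher's exact test, adjusted p = 0.0304).

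**Figure D4:**
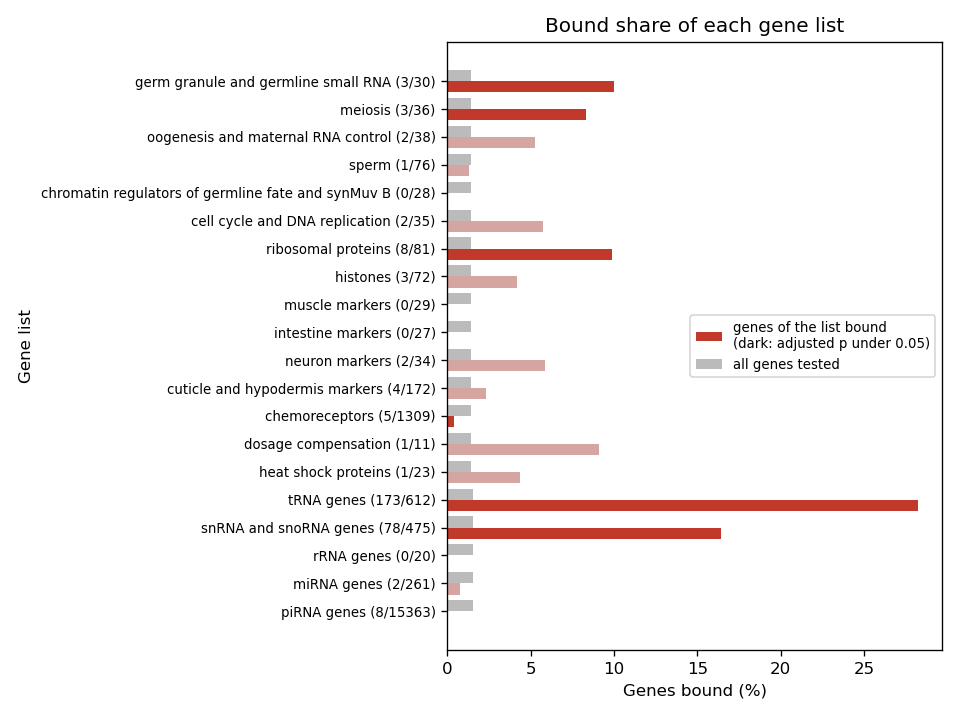
Percent of the genes of each list that were bound, with the number bound and the list size in the label, beside the percent of all genes tested. tRNA genes reached 28.3% and snRNA and snoRNA genes 16.4%, against 1.55% of all annotated genes.

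The tagged gene was examined as a check of the transgene. mes-4 (V, 13433050 to 13437545) carried a reproducible peak (V, 13433495 to 13433934, signal 129.7, nuclear rank 83) with the summit in an intron, 3830 bp from the 5' end. The overlapping peak ranked 71 in replicate 1 and 267 in replicate 2. Neither neighbour, srd-17 nor col-162, had a reproducible peak. In replicate 2 alone, relaxed peaks lay in both, the highest of rank 1038 in srd-17 and of rank 3660 in col-162. Replicate 2 also held a relaxed peak between genes next to srd-17 (V, 13429872 to 13430301). Its rank of 230 was above that of the mes-4 peak in that replicate. A second reproducible peak lay in cut-2 (V, 13415379 to 13415818, signal 103.9), a gene outside the naming rule and named after its value was seen.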

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

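The tests of explanations that use ribosomal protein genes without peaks at small RNA genes, single-copy tRNA genes, the X share away from tRNA genes or at lower ranks, and the mes-4 region were chosen after the result was seen. Those of single-copy snRNA and snoRNA genes and of GC content were set beforehand. The design had 1 group, so no biological explanation of the patterns in this part was tested.

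The mitochondrial genome held 20 reproducible peaks, which were outside the comparisons and stood out because 18 of the 20 highest signals of the list were among them. Their signal ran from 179.5 to 5748.6, compared with at most 377.7 for a nuclear peak, and together they covered 73.2% of the 13794 bp mitochondrial genome.

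Most nuclear peaks lay at tRNA, snRNA and snoRNA genes. Reads shared between identical copies did not account for this alone, since 19.01% of 426 snRNA and snoRNA genes with a sequence found once, and 25% of 140 such tRNA genes, had a summit, against 0.21% and 0.27% over rotations. Copies may still add to it, as tRNA genes with over 5 copies had a summit more often (41.4%, Fisher's exact p = 0.000519), and near-identical copies were not examined. GC content was argued against, since windows on these genes held a summit 318 times as often as GC-matched windows elsewhere (287.9 to 349.0). That interval takes the rate in GC-matched windows as fixed, so it is too narrow for the ratio. Recovery of highly transcribed chromatin without binding by MES-4 stays open, and an immunoprecipitation without the tag would be needed to decide. Such recovery goes with the odds ratio of 18.2 for ribosomal protein genes without peaks at small RNA genes (Fisher's exact p = 4.67e-08). The same 8 genes were bound before and after that filter, since none of their peaks lay at a small RNA gene. The rise from 7.65 came from fewer bound genes in all, 127 after 289, so it is not separate support. For gene bodies alone in the main set the odds ratio was 2.49 (Fisher's exact test, adjusted p = 0.348).

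The X excess is consistent with the location of tRNA genes, since 4.66% (2.35 to 8.19) of the 236 peaks away from tRNA genes were on X, below its 17.7% of the genome. A higher coverage of the whole X, as the source of this excess, was argued against by the lower ranks. Of pooled regions ranked below 2000, 14.1% (13.4 to 14.8) lay on X. Peaks were called against a control and no coverage was read, so this share does not measure coverage itself. Location does not cover all of it, since 56.4% of tRNA genes with a summit within 220 bp but 45.1% of all tRNA genes were on X, and why tRNA genes on X had a summit more often was not tested.

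The peak in mes-4 may come in part from extra copies of the transgene. Outside the gene, 3 of the top 1000 pooled regions lay within 25 kb, more than in 96.5% of such windows around the 19973 protein-coding genes. That count goes with extra copies of the transgene, but the positions do not single them out. All 3 lay on the same side, in cut-2, F53F1.3 and F53F1.4. The pooled list held no region between that in cut-2 and mes-4, and none within 25 kb on the other side. The names of these genes and the window size were chosen after the values were seen, so ordinary binding there stays open.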

How the results depend on the processing

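Leaving out peaks at small RNA genes was chosen after seeing the data. The X share was 19.7% in the top 1000 pooled regions and, without peaks at small RNA genes, 6% against 17.7% over rotations (permutation p = 0.126), and 6.19% with both choices together (permutation p = 0.0052). The centre share passed the threshold among the upper 220 peaks (43.2% against 33.3% over rotations) and for the wider definition of the centre (59.1% against 50%). The gene body share was 65.9% by any overlap, below rotations but not past the threshold. The count of lists past the threshold rose from 7 to 13 in the top 1000 regions, and to 10 there without peaks at small RNA genes. It fell to 6 among the upper 220 peaks and by any overlap. It was 5 for gene bodies alone, with length-matched lists, and in the reproducible list without peaks at small RNA genes. The exon share stayed below rotations among the upper 220 peaks (7.27%), in the top 1000 (25.4%) and in single replicates (18.4% to 21.6%), and turned to 32.0% without peaks at small RNA genes. The intron share, close to rotations in the main set, lay below them and past the threshold in the top 1000 (28.5%) and without peaks at small RNA genes (17.3%), and below them but not past it in single replicates (30.5% to 32.3%; permutation p = 0.238 and 0.626). Without peaks at small RNA genes the bound share of the reproducible list was 0% for meiosis and for tRNA genes. In the top 1000 without such peaks it was 5.56% for meiosis, 0% for tRNA genes and 0.842% for snRNA and snoRNA genes. Leaving those peaks out was the only change from the same set with them. For tRNA, snRNA and snoRNA genes the low shares follow largely from that filter itself. With each replicate alone the X share ran from 25.7% to 27.3%, the promoter share from 21.1% to 23.4% and the count of lists from 8 to 10. The promoter, tRNA and snRNA and snoRNA shares, the replicate overlap and the correlation kept their direction and side of the threshold under the alternatives run. The ce10 list held 453 peaks. A stricter IDR threshold was not run because the lists hold no IDR score. No paired analysis was possible because there was 1 group. Read depth, unknown here, limits how far weak sites can be told from background.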

Other observations

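The motif test was set before its result was seen. Some snoRNA genes of this nematode carry their own promoter, and the B box (GTTCRANNC) is an internal promoter element of RNA polymerase III genes. A hypothesis was that this element marks the snRNA and snoRNA genes with a peak. It was present within 100 bp of 31 of 86 such genes with a summit (36.0%) and of 44 of 389 without one (11.3%, odds ratio 4.42, Fisher's exact p = 2.42e-07), which is consistent with the hypothesis. Among snoRNA genes the shares were 44.1% and 12.2% (odds ratio 5.67), and the difference held for those inside protein-coding genes (odds ratio 6.42) and outside them (4.61). Among snRNA genes it did not hold, with 1 of 18 against 10 of 111 (Fisher's exact p = 1). tRNA genes carried the motif in 97.8% and 95.9%, so it did not separate them (Fisher's exact p = 0.255). Neither the motif's chance rate in shuffled sequence nor polymerase III occupancy was tested.

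The RNA of RNase MRP, mrpr-1, also had a peak (II, 7200072 to 7200511, signal 144.4). The gene was named after its value was seen.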
